A study of Danio rerio with 28 samples.

How the data were processed

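RNA was measured in 28 libraries, each made from 100 mpeg1+ cells sorted by fluorescence from the dissociated brain of an adult zebrafish. Per the labels, the fish carried a green reporter driven by ccl34b.1 and a red reporter driven by mpeg1. Each fish gave a ccl34b.1+mpeg1+ and a ccl34b.1-mpeg1+ library, and of the 3 technical replicates sorted per gate, 1 was sequenced after a check of cDNA quality. The cells were released with trypsin. Per the labels' protocols, cDNA was made by Smart-seq2, which primes on the poly(A) tail and switches template at the 5' end, with 24 PCR cycles, and was then cut by a transposase and amplified for 12 more cycles. Such libraries carry no molecular identifiers, so counts are counts of amplified reads and intervals and floors given here cover counting error only. Libraries of one group came from separate fish.

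The deposited values were whole-number counts of reads per gene, in 1 table of 32520 Ensembl gene IDs by 28 libraries, and every column was matched to a sample by its title. Per the submitters' processing notes, the authors used STAR, featureCounts and DESeq2 with the GRCz11 (danRer11) build. Versions, the annotation release, the treatment of strand and the handling of multi-mapped reads were not given in the sources used here. Reads of near-identical paralogs (the immunoglobulin, cxcl11, mx and ferritin genes among them) and of overlapping or antisense genes are therefore uncertain. No genome was used here, so no coordinates are given. Gene names came from a supplied table that names 29201 of the 32520 IDs (89.8%), many with human-style symbols in capitals. A symbol carried by several IDs (6136 IDs share one) is printed with its ID. The RefSeq table was used only for synonyms, without its coordinates, which belong to another assembly (GRCz12tu).

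Comparisons were fitted with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, robust quasi-likelihood fits (glmQLFit and glmQLFTest, two-sided) and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 as the threshold. Every adjusted p for a gene comes from this test unless another tool is named. The untreated fish were fitted alone. The 18 libraries of the injection experiment were fitted as 6 groups with 1 shared estimate of the spread, since groups held 2 to 4 libraries. Fold changes are fitted log2 values with their SE, levels are CPM (computed here from the deposited counts and the scaled library totals) as mean ± SD, and folds in words are the fitted values on the linear scale, which can differ slightly from the ratio of the mean CPM beside them. Where a group held 0 counts of a gene, the fold was computed against a floor of 3 counts over the whole group and is given as "at least". With 1 to 3 counts the ratio is given with its 95% counting interval.

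Gene lists (27, holding 784 symbols, of which 729, or 93.0%, were matched) were fixed together with the groups, tests and most alternatives before the data were examined. They covered microglia identity, pan-myeloid genes, conventional dendritic cells, engulfment, lysosome, lipid transport, sterol synthesis, complement, MHC class II, MHC class I, chemokines, inflammatory genes, interferon-stimulated genes, pattern recognition, iron, glycolysis, cell cycle, immediate early and stress genes, and markers of neutrophils, T cells, NK cells, B cells, neurons, oligodendrocytes, radial glia, endothelium and erythrocytes. The microglia and dendritic cell lists may overlap with what the study itself reported of these cells, so their direction is not independent evidence. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation of 0.01, and again with an estimated correlation, adjusted over the lists of a comparison. List p-values below are from camera with the preset correlation unless they are said to use an estimated one. Of 240 list tests, 56 passed with the preset and 9 with the estimated correlation.

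Named genes followed a rule fixed in advance. It took the sort genes, then the 10 largest positive and 10 largest negative fold changes (3 and 3 in the minor comparisons) among genes past the threshold with a proper name, a mean of at least 20 CPM in the higher group and no overlap between libraries, then the 3 members of each list with the smallest adjusted p, and up to 10 interaction genes by adjusted p. Genes outside it are said to be chosen after their values were seen. The values of 1 gene that the rule names are not reported here.

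Alternatives were DESeq2 size factors, no filter, a filter at a mean of 10 CPM, DESeq2 1.42.0, limma voom with quality weights, a fold threshold of 1 on the log2 scale, other sets of libraries in the fit, other comparators, the replicate number as a block, and leaving out each library in turn. The DESeq2 and voom fits used the same libraries and filter. On simulated counts with 200 changed genes, edgeR recovered 4% of genes changed 8-fold and 10% of those changed 16-fold in the untreated gate comparison (8658 genes), calling 0 unchanged genes. For E. coli against PBS in ccl34b.1+ cells (12421 genes) the shares were 10% and 22% with 2 unchanged genes called. DESeq2 recovered 26% and 32% there with 99 unchanged genes called, and voom 10% and 12% with 11. The edgeR shares at 8-fold and 16-fold were 22% and 22% with 7 unchanged genes called in the PBS gate comparison, 14% and 10% with 3 for E. coli against PBS in ccl34b.1- cells, and 0% and 6% with 3 in the interaction, where 3 changed genes were recovered. Most changed genes of these sizes were thus not called, and some calls were of unchanged genes. The 7 unchanged calls in the PBS gate comparison stood beside 11 and 11 changed genes recovered at 8-fold and 16-fold. For E. coli against PBS, 3 stood beside 7 and 5 in ccl34b.1- cells and 2 beside 5 and 11 in ccl34b.1+ cells. No gene changed 2-fold or 4-fold was recovered by edgeR there. In these comparisons and the interaction, unchanged genes were a larger share of the calls than the adjusted p threshold. In the untreated gate comparison they were not. No library pair held identical values. Figures and checks used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Correlations across the ccl34b.1- libraries were tested with two-sided permutations, all of them within the injection experiment (9 libraries) and 100000 draws within each experiment over both (14 libraries).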

Results

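The data collected were RNA-seq counts from cells sorted from the brains of adult zebrafish into 2 gates, which the labels call microglia (the resident macrophages of the brain). Both gates expressed a reporter driven by mpeg1, a macrophage gene, and they differed in a reporter driven by ccl34b.1, a chemokine gene. Cells of the gates are called ccl34b.1+ and ccl34b.1- cells. A first experiment used 5 untreated fish aged 4 months, and a second used 9 fish aged 6 months, of which 2 were controls, 4 received PBS (the buffer alone) and 3 received E. coli. Each fish gave 1 library per gate. Library totals were 20.4 to 30.4 M counts (M, mega) for ccl34b.1+ and 14.2 to 24.0 M for ccl34b.1- cells of untreated fish. In the injection experiment they were 3.57 to 3.60 and 2.24 to 2.35 M in controls, 3.14 to 7.79 and 2.90 to 9.00 M after PBS, and 3.66 to 4.11 and 3.34 to 9.69 M after E. coli, in the same order of gates. ENSDARG00000080337, an ID with no name, was singled out after its values were seen because it took the most counts, 5.51% ± 0.806 (SD, n = 5) in ccl34b.1+ and 12.5% ± 2.55 in ccl34b.1- libraries of untreated fish.

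The gates of untreated fish were compared first, to describe how the 2 mpeg1+ populations differ. In ccl34b.1+ cells, apoc1, an apolipoprotein of lipid transport, was 49.4-fold higher, at 9202 ± 1053 against 186 ± 190 CPM (the latter 103 without ccl34b.1- library 2; SD, n = 5 and 5; log2 fold change 5.63 ± 0.60, SE; adjusted p = 0.000119). The lectin-binding scavenger gene lgals3bp.1 was 25.6-fold higher (4.68 ± 0.33, adjusted p = 4.66e-06). The ccl34b.1- cells instead held siglec15l, a sialic acid-binding lectin, at 1794 ± 1145 against 0.171 ± 0.122 CPM (log2 fold change -13.32 ± 1.01, adjusted p = 8.4e-06), and chl1a, a cell adhesion gene, at 283 ± 168 CPM against 3 counts in all 5 ccl34b.1+ libraries (ratio 10500, interval 3610 to 51100). Immunoglobulin light chain transcripts lay in ccl34b.1- cells: igl3v5 and igl4c1 had 0 counts in the 5 ccl34b.1+ libraries and 149 and 122 CPM in ccl34b.1- libraries, or 72.6 and 74.9 CPM without ccl34b.1- library 4. Of the sort genes, ccl34b.1 (ENSDARG00000093608) was 25.4-fold higher, 10040 ± 1511 against 396 ± 285 CPM (adjusted p = 1.22e-05), while MPEG1 (ENSDARG00000055290) stood at 898 ± 111 and 1174 ± 336 CPM (adjusted p = 0.717). Because ccl34b.1 drives the reporter of the sort, its difference restates the gating, in the microglia and chemokine lists as well.

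Of 19 measured microglia identity genes, 5 were higher in ccl34b.1+ cells and none lower over all genes tested, and 11 were higher when adjusted over the list alone (adjusted p = 1.15e-06 for the list, but adjusted p = 0.209 with an estimated correlation). Besides ccl34b.1, apoc1 and lgals3bp.1 these were P2RY12, a purinergic receptor of microglia, at 131 against 0.079 CPM, and apoeb, an apolipoprotein E gene, at 14070 against 92.2 CPM, both chosen after their values were seen. Conventional dendritic cell genes went the other way: 7 of 13 were lower in ccl34b.1+ cells, 9 when adjusted over the list alone, and the list passed with both settings (adjusted p = 1.4e-13, and adjusted p = 0.00085 with an estimated correlation). The immediate early and stress list, made of genes induced rapidly by stimuli or handling, had 13 of 40 members higher and none lower, and 22 higher and 2 lower when adjusted over the list alone. JUNB (ENSDARG00000104773) stood at 4555 ± 1058 against 632 ± 287 CPM, and FOS and ZFP36L1 (ENSDARG00000021443) were higher by 1.84 and 2.52 on the log2 scale. That list had an adjusted p of 0.00683, and adjusted p = 0.219 with an estimated correlation.

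In the lysosome list 6 of 59 members were higher in ccl34b.1+ cells, over all genes and adjusted over the list alone, with none lower. They included PSAP, a saposin precursor, at 4466 ± 679 against 1722 ± 227 CPM, the granulin gene grna (log2 fold change 1.54 ± 0.21) and CTSB, cathepsin B (1.68 ± 0.27), though the list as a whole had an adjusted p of 0.0544. Of 17 lipid transport genes 4 were higher and 1 lower, and 6 and 1 when adjusted over the list alone, with the lipid droplet coat gene PLIN2 10.8-fold higher (710 ± 217 against 65.4 ± 37.2 CPM) and MYLIP (ENSDARG00000055118), a ligase that degrades the LDL receptor, at least 4860-fold lower. The list did not pass (adjusted p = 0.141). HMOX1, which breaks down heme, was the iron list's single called member of 17 (2.76 ± 0.56, 589 ± 628 against 87.2 CPM, 310 without ccl34b.1+ library 2), and MYD88, the adaptor of Toll-like receptors, was higher at 1020 against 239 CPM while NOD2, an intracellular sensor, was lower (1 count against 61.4 CPM, 37.6 without ccl34b.1- library 4, ratio 8770, interval 1570 to 346000), the 2 called members of 19 pattern recognition genes.

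The chemokine genes ccl35.1 and ccl35.2 were lower in ccl34b.1+ cells (878 against 2256 and 199 against 954 CPM), and with ccl34b.1 they were the called members of 14 (3 lower and 1 higher when adjusted over the list alone; adjusted p = 0.186). Of 33 inflammatory genes il12ba, an interleukin 12 subunit (87.2 CPM in ccl34b.1- and 0.033 in ccl34b.1+ cells), and tnfb, a tumor necrosis factor, were lower and the transcription factor CEBPB higher (log2 fold change 1.74), the same numbers when adjusted over the list alone (adjusted p = 0.845). SOCS1, a brake on cytokine signalling, was the one called member of 17 interferon-stimulated genes and lower (1 count against 63.7 CPM, ratio 7700, interval 1380 to 304000). Of 22 pan-myeloid genes 1 was higher and 3 lower, 3 and 4 when adjusted over the list alone (adjusted p = 0.845). The called spi1a, a myeloid transcription factor, was not past the threshold without ccl34b.1+ library 1 (adjusted p = 0.0643). Of 14 engulfment genes rac2, a GTPase of leukocyte movement, was called and lower (209 against 740 CPM), although the list test ran upward (adjusted p = 0.0316, and adjusted p = 0.209 with an estimated correlation).

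Some markers of other cell types were called between the gates. Of 8 B cell markers igic1s1, igl3v5 and EBF1 (ENSDARG00000099849; chosen after its values were seen) were lower in ccl34b.1+ cells and XBP1 higher, with 5 lower and 2 higher when adjusted over the list alone (adjusted p = 0.00028, and adjusted p = 0.209 with an estimated correlation). The light chain sum in ccl34b.1- libraries 1 to 5 was 7.27, 277, 445, 1505 and 631 CPM, so its level varied widely between fish. The chemokine receptors CCR9 (ENSDARG00000055186; 304 ± 46.5 against 1496 ± 880 CPM), a called T cell marker of 2, and CXCR4 (ENSDARG00000057633; 1 count against 230 ± 173 CPM, ratio 32500, interval 5840 to 1290000) were lower, and the T cell list had an adjusted p of 0.0316, and adjusted p = 0.218 with an estimated correlation. Of 7 radial glia markers 2 were higher in ccl34b.1+ cells, among them GLUL (ENSDARG00000099776; glutamine synthetase, 2016 ± 641 against 182 ± 139 CPM; list adjusted p = 0.172). HSD17B7 was the called member of 10 sterol synthesis genes, and its call did not hold without ccl34b.1+ library 1, 2, 3 or 4 (adjusted p = 0.0535 to 0.0651). No list member passed in the complement (6 measured), MHC class II (14), MHC class I (24), glycolysis (20), cell cycle (7), neutrophil (3), oligodendrocyte (3) and endothelial (6) lists, and NK cell, neuron and erythrocyte markers were not measured.

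The edgeR test covered 8658 genes, of which 321 passed, 182 higher and 139 lower in ccl34b.1+ cells, and 914 had an unadjusted p under 0.05. Named genes with 0 counts in ccl34b.1- libraries of untreated fish included ptx4, a pentraxin (72.7 ± 44.7 CPM, at least 2170-fold), and ANGPTL4, an inhibitor of lipoprotein lipase (66.3 ± 16.1 CPM, at least 1980-fold). Of 50 named genes called, 41 passed in each of the 10 fits that left out 1 library, a larger share than in the comparisons of 6-month fish that follow (8 of 27 in the control gate comparison and 11 of 32 for E. coli against PBS in ccl34b.1- cells). The count was 583 with DESeq2, 602 with voom and 782 when all 28 libraries shared the fit, and it fell with the replicate number as a block (given below).

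**Figure D1:**
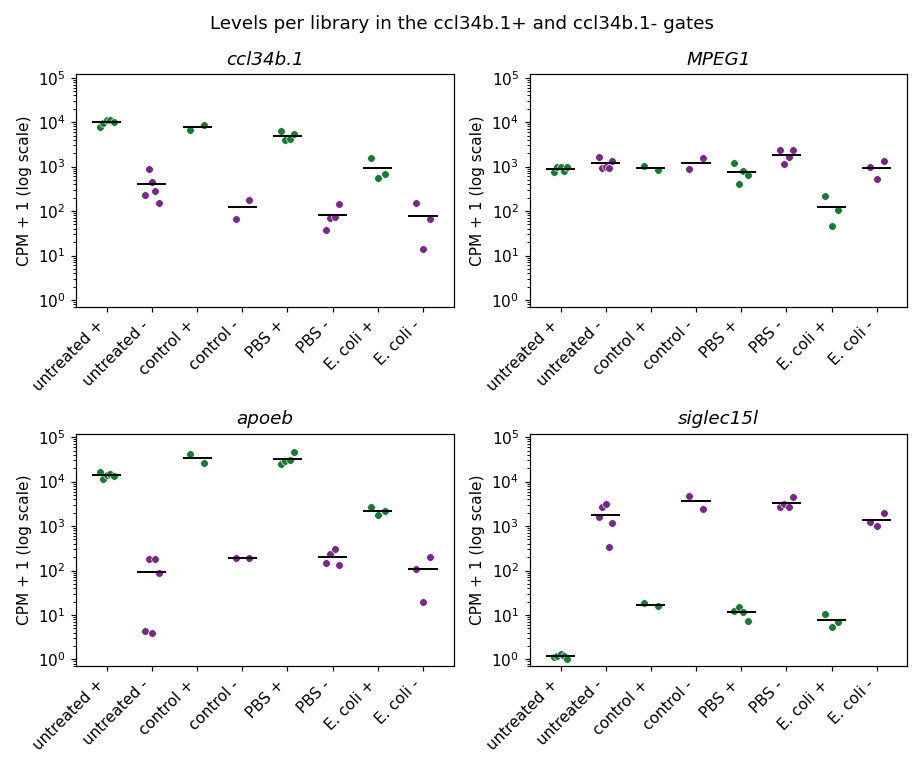
CPM plus 1 on a log axis for ccl34b.1, MPEG1, apoeb and siglec15l in the 8 groups of libraries, each point a library and each line a group mean. The siglec15l means were 0.171 CPM in ccl34b.1+ and 1794 CPM in ccl34b.1- cells of untreated fish.

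The gate comparison was repeated in 6-month fish. After PBS, apoc1 was 151-fold higher in ccl34b.1+ cells (6775 ± 2123 against 44.8 ± 10.7 CPM, n = 4 and 4; log2 fold change 7.24 ± 0.43, adjusted p = 6.15e-14), apoeb stood at 33000 ± 9749 against 203 ± 77.7 CPM, and il6, the interleukin 6 gene, was 17.0-fold higher (281 ± 94.9 against 16.5 ± 6.42 CPM). In ccl34b.1- cells siglec15l stood at 3226 ± 814 against 10.8 CPM, the adhesion gene HEPACAM2 at 900 against 2.50 CPM, and ccl19a.1, a chemokine gene, was 118-fold higher (6159 ± 1160 against 52.2 CPM; log2 fold change -6.88 ± 0.39 for ccl34b.1+ against ccl34b.1-). In control fish apoc1 was higher (9514 ± 137 against 97.6 ± 69.6 CPM, n = 2 and 2) and siglec15l and ccl19a.1 were lower (log2 fold changes -7.79 ± 0.63 and -7.47 ± 0.57). After E. coli apoc1 was higher (981 ± 162 CPM in ccl34b.1+ cells, n = 3 and 3; log2 fold change 5.68 ± 0.46), and siglec15l and ccl19a.1 were lower (log2 fold changes -7.69 and -8.36 ± 0.48). The sort gene ccl34b.1 was 62.2-fold higher after PBS (4934 ± 1107 against 79.2 ± 43.6 CPM). It was called in control fish (log2 fold change 6.01 ± 0.98, adjusted p = 0.00308), but not without control ccl34b.1+ library 2 (adjusted p = 0.0501) or ccl34b.1- library 1 (0.28) or 2 (0.0887). After E. coli it was at 924 ± 535 against 77.2 ± 71.4 CPM (adjusted p = 0.00916, and 0.0614 without ccl34b.1- library 3; 38.8 CPM without ccl34b.1- library 1).

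Dendritic cell genes were lower in ccl34b.1+ cells of all 3 treatments: 8 of 16 in control, 11 after PBS and 9 after E. coli, or 10, 12 and 12 when adjusted over the list alone. The list had an adjusted p of 9.86e-19, 1.87e-19 and 1.41e-15, and adjusted p = 0.00395, 0.00333 and 0.00878 with an estimated correlation. Microglia identity genes were higher, 4 of 20 in control and 7 after PBS, and 11 and 12 when adjusted over the list alone (1 and 2 lower), with an adjusted p of 2.01e-09 and 2.79e-07, but adjusted p = 0.0692 and 0.0884 with an estimated correlation. After E. coli 4 were higher and 3 lower, 8 and 3 when adjusted over the list alone (adjusted p = 0.0036, and adjusted p = 0.203 with an estimated correlation). Immediate early genes were higher in control (8 of 41, with DUSP2, a phosphatase of kinase signalling, at 5744 against 100 CPM; adjusted p = 9.44e-07, and adjusted p = 0.108 with an estimated correlation) and after PBS (12 higher and 2 lower, with JUNB ENSDARG00000104773 higher by 3.33 and EGR3 by 4.43 on the log2 scale; adjusted p = 0.000544, and adjusted p = 0.321 with an estimated correlation). Adjusted over the list alone these were 21 higher, and 20 higher and 5 lower. After PBS 5 of 20 lipid transport genes were higher, 5 also when adjusted over the list alone (adjusted p = 0.114).

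After E. coli the gates also differed in other groups. MPEG1 was lower in ccl34b.1+ cells (122 ± 84 against 943 ± 414 CPM, the former 76.5 without ccl34b.1+ library 1; log2 fold change -2.95 ± 0.50, adjusted p = 0.00034), while NCF1, a subunit of the NADPH oxidase that makes superoxide, was higher (5098 ± 836 against 734 ± 421 CPM), as was il1b, the interleukin 1 beta gene (17500 ± 5437 against 628 ± 699 CPM, the latter 232 without ccl34b.1- library 2). Among 22 pan-myeloid genes 7 were higher and 3 lower, 12 and 4 when adjusted over the list alone (adjusted p = 0.00197, and adjusted p = 0.134 with an estimated correlation). Of 43 inflammatory genes 5 were higher and 2 lower, 10 and 6 when adjusted over the list alone (adjusted p = 0.00365, and adjusted p = 0.0961 with an estimated correlation). MHC class II genes, which present antigen to T cells, were lower in 5 of 13 cases, 7 lower and 1 higher when adjusted over the list alone, among them the invariant chain gene cd74b (log2 fold change -1.61 ± 0.32), cd83 (158 against 1623 CPM, 88.9 without ccl34b.1+ library 1) and ifi30a, a thiol reductase of antigen processing (-3.14), with an adjusted p of 0.00283, and adjusted p = 0.203 with an estimated correlation. Of 24 chemokines 2 were higher and 7 lower, 4 and 8 when adjusted over the list alone (adjusted p = 0.0291, and adjusted p = 0.329 with an estimated correlation). Sterol synthesis genes tended upward as a list (17 of 19 with a positive value; adjusted p = 3.79e-05, and adjusted p = 0.0297 with an estimated correlation), with no single member past the threshold.

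Of endothelial markers after PBS, pecam1a, an adhesion gene of endothelium, was higher in ccl34b.1+ cells (189 ± 69.4 against 1.35 CPM) and rgs5b, a gene of mural cells, was at 339 against 12.9 CPM (8.44 without ccl34b.1- library 3), 2 of 7 measured (3 when adjusted over the list alone; adjusted p = 0.0168, and adjusted p = 0.0884 with an estimated correlation). The B cell list was lower in ccl34b.1+ cells after PBS (1 of 14 higher and 1 lower, and 2 and 9 when adjusted over the list alone; adjusted p = 0.00433, and adjusted p = 0.1 with an estimated correlation). The T cell list was lower in control and PBS fish (adjusted p = 0.00736 and 0.0193, and adjusted p = 0.0692 and 0.0884 with an estimated correlation), with no called member of 7 in either. In control fish 1 of 24 chemokines was higher and 5 lower, 1 and 6 when adjusted over the list alone (adjusted p = 0.00433, and adjusted p = 0.228 with an estimated correlation), and the cell cycle list was higher with no member of 24 past the threshold (adjusted p = 0.00286, and adjusted p = 0.1 with an estimated correlation).

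The edgeR fit of 12421 genes called 108 in control (63 higher and 45 lower in ccl34b.1+ cells), 334 after PBS (150 and 184) and 287 after E. coli (110 and 177). The median log2 fold change after PBS was -0.108, and -0.231 with DESeq2 size factors. In control fish the count was 49 or 61 without ccl34b.1+ library 1 or 2 and 38 or 56 without ccl34b.1- library 1 or 2, and after E. coli it was 188, 177 or 162 without ccl34b.1+ library 1, 2 or 3. DESeq2 called 456, 1102 and 1589 genes and voom 662, 714 and 464 in the 3 treatments, and the E. coli count was 112 in a fit of its own libraries. With the replicate number as a block the control count rose (given below).

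The experiments shared no library. Of 311 genes called in untreated fish and measured in both, 94.5% (exact 95% interval 91.4 to 96.8) had the same sign in PBS fish, 96.1% (93.4 to 98.0) in control and 82.0% (77.3 to 86.1) in E. coli fish. The intervals count genes, which are not independent replicates, so they do not measure the spread between fish. Across 8201 genes, to which the same applies, the log2 fold changes correlated with r = 0.428, 0.441 and 0.264. In PBS fish 55 genes were higher in both experiments (2.95 by chance) and 68 lower in both (2.56 by chance), and in E. coli fish 31 (2.26) and 52 (2.76), with 1 gene called in opposite directions.

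**Figure D2:**
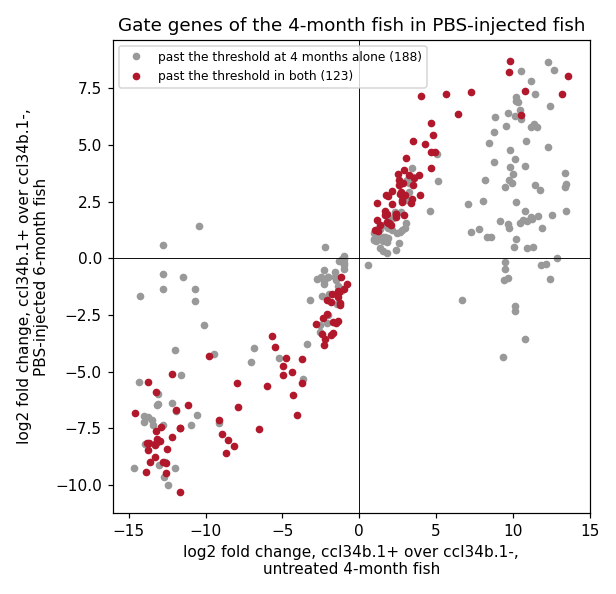
Log2 fold change of ccl34b.1+ against ccl34b.1- cells in untreated fish (x axis) and in PBS fish (y axis), each point one of the 311 genes called in untreated fish. The 123 genes also past the threshold in PBS fish are drawn apart from the other 188, and 94.5% of all points had the same sign in both.

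E. coli was compared with PBS within each gate, to describe the response to bacteria. In ccl34b.1+ cells inflammatory genes rose. NCF1 was 21.1-fold higher after E. coli (5098 ± 836 against 242 ± 95.1 CPM, n = 3 and 4; log2 fold change 4.40 ± 0.46, adjusted p = 2.12e-07), cxcl8a, a chemokine that draws neutrophils, 47.0-fold (1881 ± 351 against 40.1 ± 39.7 CPM, the latter 22.8 without PBS library 2) and mxf, an interferon-induced antiviral GTPase, 549-fold (3852 ± 318 against 7.07 ± 4.92 CPM). The control libraries held cxcl8a at 110 and 131 CPM, so its fold against PBS is larger than against control fish. The MHC class II chaperone gene cd74a fell from 36920 ± 16120 to 6183 ± 3686 CPM (4062 without E. coli library 1; log2 fold change -2.58 ± 0.35), apoeb from 33000 ± 9749 to 2221 ± 480 CPM (-3.89 ± 0.62) and MPEG1 from 757 to 122 CPM (-2.64 ± 0.48, adjusted p = 0.00101; 76.5 CPM without E. coli library 1). The sort gene ccl34b.1 was at 924 ± 535 against 4934 ± 1107 CPM, short of the threshold (adjusted p = 0.0855).

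Of 43 inflammatory genes 8 rose and none fell, and 21 rose and 1 fell when adjusted over the list alone (adjusted p = 2.64e-15, and adjusted p = 0.000196 with an estimated correlation), among them nfkbiaa, an inhibitor of NF-kB that NF-kB itself induces (log2 fold change 3.33). The summed level of that list was 57160 ± 9124 CPM against 15070. Of 22 pan-myeloid genes 6 rose and 3 fell, 8 and 3 when adjusted over the list alone (adjusted p = 0.000101, and adjusted p = 0.0814 with an estimated correlation). MFAP4 (ENSDARG00000089667), a macrophage gene, rose 13.6-fold and ARPC1B, an actin-branching subunit, fell (log2 fold change -2.45). Interferon-stimulated genes rose in 3 of 34 cases, 3 when adjusted over the list alone, and summed to 7015 ± 857 against 1018 CPM (adjusted p = 0.00144, and adjusted p = 0.127 with an estimated correlation). Of 24 chemokines 3 rose, including cxcl8a and cxcl11.1, a ligand of the CXCR3 receptors (733 ± 99.8 against 3.29 CPM), and 3 rose and 2 fell when adjusted over the list alone (adjusted p = 0.184). In the iron list 3 of 21 rose, 4 when adjusted over the list alone, with the ferritin gene fth1a at 1661 ± 981 against 193 CPM (adjusted p = 0.028, and adjusted p = 0.153 with an estimated correlation). Of 25 glycolysis genes 2 rose and 1 fell, 5 and 1 when adjusted over the list alone, among them the sugar transporter SLC2A6 (2812 against 114 CPM; adjusted p = 0.00216, and adjusted p = 0.149 with an estimated correlation). The sterol synthesis list rose as a whole (18 of 19 positive; adjusted p = 1.87e-05, and adjusted p = 0.0271 with an estimated correlation) with no single member past the threshold.

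Among lists that fell, 5 of 20 microglia genes were lower, 9 when adjusted over the list alone (adjusted p = 7.35e-06, and adjusted p = 0.127 with an estimated correlation), with apoc1 at 981 ± 162 against 6775 ± 2123 CPM and the complement gene c1qb at 22.1 against 347 CPM (3.83 without E. coli library 1). The list summed to 8037 ± 2166 CPM after E. coli and 63000 ± 11080 after PBS. Of 13 MHC class II genes 5 fell, 6 when adjusted over the list alone (adjusted p = 8.35e-05, and adjusted p = 0.149 with an estimated correlation), among them cd74b and ifi30a (log2 fold changes -2.92 ± 0.33 and -4.39 ± 0.63). Immediate early genes fell in 8 of 41 cases and rose in 1, and 21 and 1 when adjusted over the list alone (adjusted p = 0.00092, and adjusted p = 0.286 with an estimated correlation), among them FOS (log2 fold change -3.31), EGR3 (-3.77) and JUNB ENSDARG00000074378 (1773 against 7680 CPM). XBP1, a transcription factor of the unfolded protein response, fell from 7431 to 1905 CPM as the called member of 14 B cell markers, and 1 of 10 complement genes fell (4 when adjusted over the list alone; adjusted p = 0.0329, and adjusted p = 0.286 with an estimated correlation). The neutrophil list tended upward with no member past the threshold (adjusted p = 0.0329, and adjusted p = 0.282 with an estimated correlation), and 1 lysosome gene of 65 rose and 1 fell, 3 and 1 when adjusted over the list alone (adjusted p = 0.028, and adjusted p = 0.149 with an estimated correlation). Of 20 lipid transport genes 2 fell (adjusted p = 0.168), 1 engulfment gene of 19 fell, and 1 of 24 pattern recognition genes rose and 2 fell. No member of the dendritic cell, MHC class I, cell cycle, T cell, oligodendrocyte, radial glia, endothelial, NK cell, neuron or erythrocyte lists was called.

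The test called 188 genes in ccl34b.1+ cells, 87 higher and 101 lower after E. coli, with 1970 at an unadjusted p under 0.05 and a median log2 fold change of -0.185. Of 49 named genes called, 25 passed in all 7 fits that left out 1 library, among them FES, a tyrosine kinase of myeloid cells (466 ± 98.6 CPM after E. coli; log2 fold change 8.56 ± 0.80), and the count was 101 without E. coli library 2. The count was 981 with DESeq2, 659 with voom and 320 in a fit of these libraries alone.

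In ccl34b.1- cells several chemokine genes rose after E. coli. The gene cxcl11.5 rose 157-fold (824 ± 372 against 5.30 ± 5.24 CPM, the latter 2.95 without PBS library 1, n = 3 and 4; log2 fold change 7.29 ± 1.00, adjusted p = 0.000326), cxcl11.6 77.4-fold (723 ± 478 against 9.35 ± 3.56 CPM, 474 without E. coli library 1) and cxcl11.7 56.3-fold (1061 ± 514 against 18.9 ± 10.5 CPM). The control libraries held more cxcl11.5 (75.3 ± 65.7 CPM) and cxcl11.6 (36.2 and 51.5 CPM) than the PBS means. Folds of these genes against PBS are thus larger than against control fish. The cystine transporter gene slc7a11 rose (266 ± 167 against 4.07 CPM, 173 without E. coli library 2 and 2.15 without PBS library 2), as did LTB4R, a receptor for leukotriene B4 (46.6 against 0.21 CPM, 24.5 without E. coli library 2). LCP1, an actin-bundling protein of leukocytes, fell from 3047 ± 534 to 946 ± 33.4 CPM (log2 fold change -1.69 ± 0.31, adjusted p = 0.00603). The sort genes were short of the threshold, at log2 fold changes of -0.04 for ccl34b.1 and -0.98 for MPEG1 (adjusted p = 0.241).

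Of 24 chemokines 5 rose and none fell, and 10 rose and 3 fell when adjusted over the list alone (adjusted p = 3.27e-05, and adjusted p = 0.267 with an estimated correlation). Of 43 inflammatory genes 3 rose, 9 when adjusted over the list alone, and the list passed with both settings (adjusted p = 4.4e-06, and adjusted p = 0.0134 with an estimated correlation). NCF1 was among them (734 against 187 CPM, adjusted p = 0.0198), but its call did not hold without PBS library 1 (0.101) or 3 (0.0911) or E. coli library 2 (0.105) or 3 (0.107). Of 34 interferon-stimulated genes 2 rose, 3 rose and 1 fell when adjusted over the list alone, and their sum was 4066 ± 1788 against 910 CPM (adjusted p = 0.0723). The neutrophil list had 1 called member of 7, the collagenase gene mmp13a (adjusted p = 0.0181), whose call did not hold without any 1 of the 4 PBS libraries (0.0518 to 0.0764) or E. coli library 2 (0.219), and 5 rose and 1 fell when adjusted over the list alone (adjusted p = 0.00166, and adjusted p = 0.265 with an estimated correlation). The glycolysis list had 1 called member of 25, the hexokinase gene HK2 (log2 fold change 2.91), whose call did not hold without PBS library 1 (adjusted p = 0.0646) or E. coli library 2 (0.0599), and 2 when adjusted over the list alone (adjusted p = 0.0451, and adjusted p = 0.43 with an estimated correlation). Of 22 pan-myeloid genes 1 rose and 2 fell, and in the immediate early list egr1 fell (log2 fold change -2.45, adjusted p = 0.00838, and 0.0541 without PBS library 3). In the dendritic cell list 1 of 16 fell (4 when adjusted over the list alone; adjusted p = 0.0723), and no microglia or MHC class II gene was called.

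The test called 50 genes in ccl34b.1- cells, 29 higher and 21 lower (24 and 36 with DESeq2 size factors, which moved the median log2 fold change from -0.078 to -0.287), with 2419 at an unadjusted p under 0.05. The count was 32 without PBS library 1, 31 without PBS library 3, 26 without E. coli library 2 and 90 without E. coli library 3. DESeq2 called 1194 genes, 95 were called against PBS and control fish averaged, and 9 in a fit of these libraries alone. The comparisons of the 2 gates share no library, although each fish gave both gates. In both, 13 genes rose (0.203 by chance from the numbers called) and 5 fell (0.171 by chance), and edgeR called none in opposite directions.

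**Figure D3:**
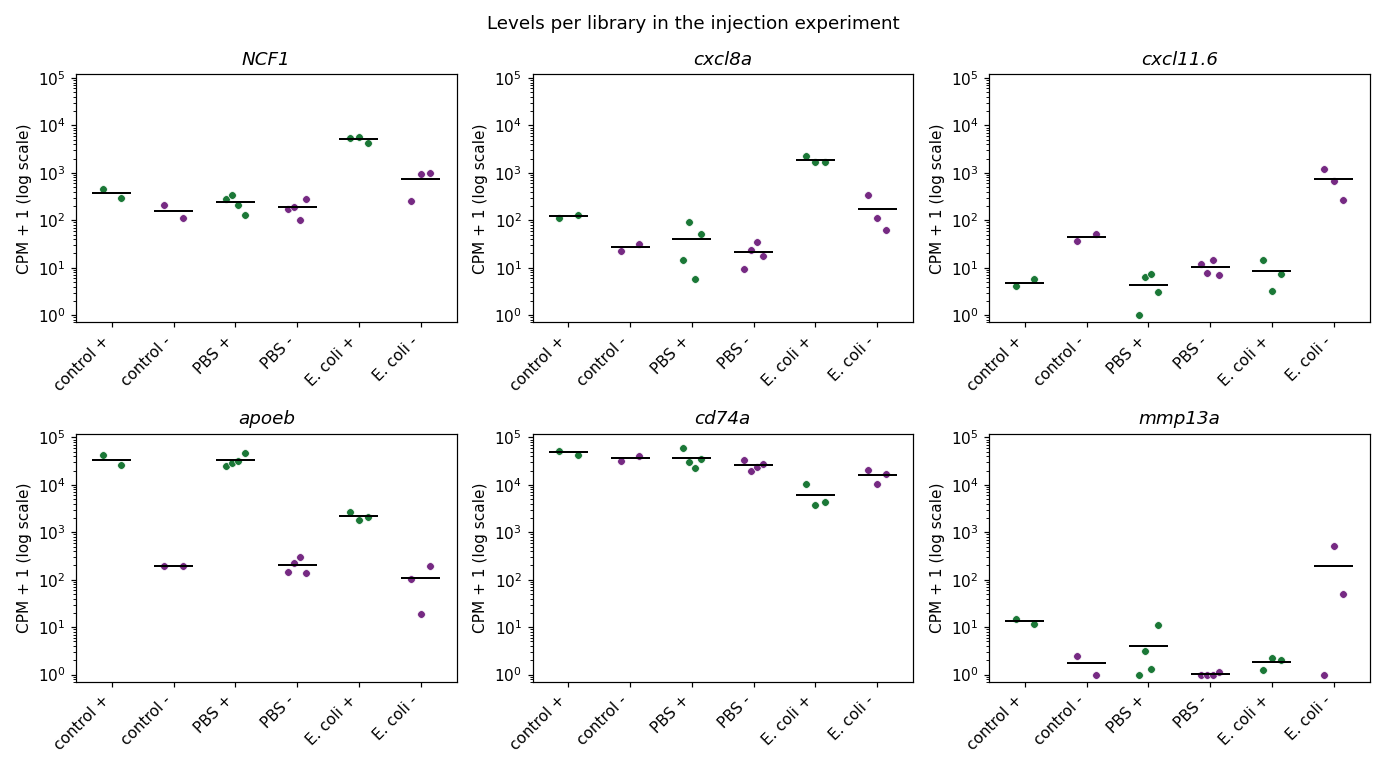
CPM plus 1 on a log axis for NCF1, cxcl8a, cxcl11.6, apoeb, cd74a and mmp13a in the 6 groups of the injection experiment, each point a library and each line a group mean. In ccl34b.1+ cells the apoeb mean was 33000 CPM after PBS and 2221 CPM after E. coli.

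Whether the response differed between the gates was tested as an interaction. FES rose in ccl34b.1+ cells from 1.2 to 466 CPM and was at 268 and 101 CPM in ccl34b.1- cells, an interaction of 9.96 on the log2 scale (adjusted p = 8.54e-07). The axon guidance gene sema4ab (37.0 to 792 CPM against 284 and 147), AIF1L, an actin-binding gene (27 to 257 against 727 and 499), marcksl1a (434 to 2642 against 850 and 718) and the g-type lysozyme gene lygl1 (174 to 3704 against 453 and 1461) went the same way. XBP1 and DDIT3, both of the unfolded protein response, and TTYH3 ENSDARG00000034473 had negative interactions of -2.56, -2.88 and -6.32, with DDIT3 at 6325 and 964 CPM in ccl34b.1+ cells after PBS and E. coli and 1073 and 1206 in ccl34b.1- cells. These 8 genes passed in all 14 fits that left out 1 library. For cxcl11.5 the interaction was -7.02 (adjusted p = 0.0506 without E. coli ccl34b.1+ library 2). The interaction was not past the threshold for NCF1 (adjusted p = 0.0793), cd74a (0.0807) or cd74b (0.0784).

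Of the lists, pan-myeloid genes had a positive interaction (adjusted p = 0.000679, and adjusted p = 0.24 with an estimated correlation; 1 of the 22 called, and 5 positive and 1 negative when adjusted over the list alone). The inflammatory and sterol lists were positive too (adjusted p = 0.0314 and 0.0447, and adjusted p = 0.24 and 0.488 with an estimated correlation). The microglia, MHC class II and chemokine lists were negative (each adjusted p = 0.0447, and adjusted p = 0.661 with an estimated correlation). The test called 34 genes, 16 positive and 18 negative (18 and 11 with DESeq2 size factors, which moved the median from -0.178 to 0.021). That count was 17, 20, 17 and 20 without PBS ccl34b.1+ libraries 1 to 4, 20 and 21 without PBS ccl34b.1- libraries 3 and 4, 14 without E. coli ccl34b.1+ library 2, and 55 and 21 without E. coli ccl34b.1- libraries 2 and 3. It was 596 with DESeq2, and it also rose with the replicate number as a block (given below).

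PBS fish were compared with the control group as the background of the injection experiment (n = 4 and 2). The cell cycle list fell in ccl34b.1+ cells, with 22 of 24 members negative and none past the threshold (adjusted p = 4.12e-08, and adjusted p = 0.0172 with an estimated correlation). Its summed level was 937 and 430 CPM in the 2 control libraries and 160 to 294 CPM after PBS. Untreated ccl34b.1+ libraries alone ran from 57.0 to 942 CPM. Members lay near the floor, such as bub1ba at 13.3 ± 18.8 CPM in control and 0.0738 CPM after PBS. The heat shock genes HSP90AA1, hsp70.1 and hsp70l had log2 fold changes of -1.83, -2.07 and -2.34 in ccl34b.1+ cells, short of the threshold (adjusted p = 0.876 to 0.965), and the immediate early list had an adjusted p of 0.0053, and adjusted p = 0.912 with an estimated correlation. Chemokine genes moved both ways in these cells, also short of the threshold, with ccl34a.4 at 3.44 (adjusted p = 0.35) and ccl35.1 at -1.67 (adjusted p = 0.446). No list passed in ccl34b.1- cells, where cxcl11.5 was at 5.30 ± 5.24 CPM after PBS and 75.3 ± 65.7 CPM in control fish (adjusted p = 0.442). The edgeR test called 0 genes in either gate, with 628 and 642 at an unadjusted p under 0.05. These numbers are close to the 5% of 12421 tested genes that chance alone gives. DESeq2 called 83 and 126 genes and voom 207 and 41.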

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

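The tests of B cells, of RNA carry-over, of cells from the other gate, of replaced microglia and of neutrophils, and the fits on thinned counts, were chosen only after the results they bear on were seen.

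Some libraries stood apart from their group, with a gap to the nearest library that was a large share of the group's range (Dixon's ratio, above its critical value at 95% confidence). This was 18 of 297 values checked, and chance gives about 5%. Only the untreated and PBS groups were checked, and the control and E. coli groups, of 2 and 3 libraries, were not. PBS ccl34b.1+ library 1 (7.79 M counts, ratio 0.977) and PBS ccl34b.1- library 4 (9.00 M, 0.95) were deeper than the others. Interferon-stimulated genes summed to 2184 CPM in untreated ccl34b.1+ library 3 (0.755) and 1830 CPM in untreated ccl34b.1- library 5 (0.83), and cell cycle genes to 942 CPM in untreated ccl34b.1+ library 2 (0.714). T cell markers summed to 963 CPM in PBS ccl34b.1- library 1 (0.904), which also stood apart in CXCR4 ENSDARG00000057633 (0.909) and, at the low end, marcksl1a (0.87). Oligodendrocyte markers summed to 991 CPM in untreated ccl34b.1- library 2 (0.758). Untreated ccl34b.1- library 4 stood apart in its B cell marker sum (6943 CPM, 0.755) and in igl3v5 (0.71), XBP1 (0.737), MYC ENSDARG00000007241 (0.846) and ZMYND8 ENSDARG00000011932 (0.951). That sum includes XBP1, at 3360 CPM in this library. It ran from 3619 to 8515 CPM in untreated ccl34b.1+ libraries, so it does not by itself measure B cell content. The other single genes were pglyrp5 in untreated ccl34b.1- library 3 (ratio 1), lygl1 in untreated ccl34b.1+ library 3 (0.886), cxcl8b.1 in PBS ccl34b.1+ library 2 (0.882) and, at the low end, cxcl11.3 in PBS ccl34b.1- library 2 (0.874).

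The interaction test called 34 genes as differing between the gates in their response to E. coli. When this test was simulated, 3 unchanged genes were called beside 3 changed ones, so some of the 34 may not differ. As the log2 change in ccl34b.1+ cells minus that in ccl34b.1- cells, the difference was positive for FES (9.96 on the log2 scale), sema4ab (5.37), AIF1L (3.78), marcksl1a (2.85) and lygl1 (2.72). It was negative for cxcl8b.1 (-11.05; adjusted p = 0.0795 without PBS ccl34b.1+ library 2, which held most of its counts), cxcl11.5 (-7.02; 0.0506 without E. coli ccl34b.1+ library 2), TTYH3 ENSDARG00000034473 (-6.32), DDIT3 (-2.88) and XBP1 (-2.56). The count without single libraries ran from 14 to 55.

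B cell transcripts lay in the ccl34b.1- libraries, with a light chain mean of 247 CPM against 0.174 CPM in the ccl34b.1+ libraries over both experiments, or 150 CPM without untreated library 4 (1505 CPM). The ccl34b.1- group means were 573 in untreated, 69.4 in control, 72.9 in PBS and 54.5 in E. coli fish. Single libraries weighed on each, with ranges of 7.27 to 1505, 10.5 to 128, 3.39 to 155 and 30.8 to 97.6 CPM in that order. Carry-over of RNA between libraries would need a larger share than the 0.0703% found (0.116% without untreated ccl34b.1- library 4, 0.403% in the injection experiment), and a difference in depth is argued against by the 3 B cell list members still called after all libraries were thinned to 1 total. B cells among the sorted cells may be the source, but over the 9 ccl34b.1- libraries of the injection experiment light chain and other B cell transcripts were short of the threshold (rho = 0.683, exact permutation p = 0.0503; Pearson r = 0.664, exact permutation p = 0.0506, both 0.0506 after adjustment for 4 tests, and r = 0.768 without the 2 libraries farthest from the median). Over all 14, permuted within each experiment in a test added later, they did rise together (rho = 0.908, permutation p = 0.00115, adjusted 0.0046; r = 0.879, permutation p = 0.00347, adjusted 0.00694, and r = 0.796 without the 2 farthest), though the levels differ between the experiments, and the 5 untreated libraries had the same order on both measures, with no correlation computed over so few. This speaks for B cells without settling it. B cells would have to carry the mpeg1 reporter to pass the gate, and whether they do was not tested. No biological difference between the gates was tested as the cause either.

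Of 20 microglia genes 5 fell in ccl34b.1+ cells after E. coli, while the list itself had adjusted p = 0.127 with an estimated correlation. Dendritic cells of the ccl34b.1- gate among them are argued against as the sole source. Abundant dendritic cell genes reached a median of 1.43% of their ccl34b.1- level (8 genes, the highest being IRF8 at 35.3%) where a share of 87.3% would be needed. Other cells of that gate were not covered by these genes. Depth and scaling are argued against by 5 of 5 called microglia genes still called lower with size factors and with thinned counts. Replacement of microglia in the gate by another myeloid type may lower the whole list: 14 of 20 members were lower by over 1 on the log2 scale and 6 were within 1 of no change. A lower expression of these genes in the same cells after E. coli, the difference the design names, would look alike, so these cannot be told apart.

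The proteases MMP9 and mmp13a were high in ccl34b.1- cells of 2 of the 3 E. coli fish, at 0, 1190 and 2170 CPM and at 0, 525 and 49.0 CPM in libraries 1 to 3. MMP9 was short of the threshold (adjusted p = 0.176), and the call of mmp13a rests on few fish, with an adjusted p of 0.219 without E. coli library 2, 0.00356 and 0.0128 without library 1 and 3, and 0.0518 to 0.0764 without any 1 of the 4 PBS libraries. Neutrophils may be a source: the other neutrophil markers summed to 125, 358 and 745 CPM in the E. coli libraries against at most 107 in PBS libraries. In libraries 1 and 3 that sum came mainly from LECT2 ENSDARG00000090889 and il6r, also high in ccl34b.1+ libraries, but in library 2 these gave 63.5 and 46.0 CPM, and the narrower markers npsn, scpp8 and mmp25b, a measure added after the first sum was seen, gave 0.406, 59.9 and 0.101 CPM, so the test does not decide. The neutrophil lysozyme gene lyz had 0 counts in the 28 libraries, neutrophils would need the mpeg1 reporter to pass the gate, and an effect of E. coli on the sorted cells themselves stays open and untested.

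Counts of called genes were set against other splits of the same libraries. No other split reached the real count for the gate difference in untreated fish (321 genes; highest other split 1; 1 of 100 splits drawn reached the real count, the real one) and in PBS fish (334; highest other 1; 1 of 35), and for E. coli against PBS in ccl34b.1+ cells (188; highest other 32; 1 of 35) and in ccl34b.1- cells (50; highest other 20; 1 of 35). With 35 splits the share cannot fall below 1 of 35, and shares were not adjusted over the comparisons. Splits that mix the groups also carry the group difference as spread, which lowers their counts, so chance is not excluded. For the gate difference after E. coli (287; highest other 3; 1 of 10) the splits are too few for a share under 0.05. For the interaction 2 of 100 splits reached 34, and the highest other gave 176, which points to a structure of the samples: it nearly exchanged the PBS and E. coli libraries of ccl34b.1- cells, so the treatment effect shared by the gates entered it.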

How the results depend on the processing

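The thinned counts and the untreated fit without ccl34b.1- libraries 1 and 4 were tests chosen only after the data were seen. The counts of called genes kept their size (within 1.5 times) in all 9 comparisons only with DESeq2 size factors, with the added fold threshold and with thinned counts, and the cause of the moves below was not tested. In the order gate difference in untreated, control, PBS and E. coli fish, E. coli against PBS in ccl34b.1+ and ccl34b.1- cells, interaction, and PBS against control in ccl34b.1+ and ccl34b.1- cells, DESeq2 called 583, 456, 1102, 1589, 981, 1194, 596, 83 and 126 genes. With voom the counts were 602, 662, 714, 464 and 659 for the first 5, and 207 and 41 for PBS against control. Without a filter they were 175 (control gate), 472 (E. coli gate), 284, 178, 146, 21 and 13, and with a mean of at least 10 CPM PBS against control in ccl34b.1+ cells gave 1. All 28 libraries in the untreated fit gave 782, and fits of a contrast's own libraries gave 112 (E. coli gate), 320, 9 and 3 (PBS against control, ccl34b.1+). With control and PBS fish averaged as comparator E. coli gave 95 in ccl34b.1- cells, while control fish alone gave 152 and 34. Without ccl34b.1- libraries 1 and 4 the untreated count was 243.

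Leaving out each library in turn gave 231 to 315, 38 to 61, 227 to 308, 162 to 351, 101 to 162, 26 to 90, 14 to 55, 0 to 0 and 0 to 1 genes in the same order. The edgeR counts of 0 stood beside 628 and 642 genes at an unadjusted p under 0.05, close to the 5% of 12421 that chance alone gives. Signs of log2 fold changes turned for 3 values short of the threshold and for 1 called value, none past it once turned. These were MPEG1 ENSDARG00000055290, gate difference in control 6-month fish (-0.694 to 0.069, positive without ccl34b.1- library 2), ccl34b.1, PBS against control in ccl34b.1- cells (-1.12 to 0.282, positive without control library 2), ccl34b.1, E. coli against PBS in ccl34b.1- cells (-1.03 to 0.464, with 0.389, 0.464 and 0.012 without PBS library 4, E. coli library 2 and 3), and havcr2, gate difference in E. coli-injected fish, which was called at -5.48 (adjusted p = 0.0343; -6.06 to 0.824, positive with adjusted p = 0.762 without ccl34b.1- library 3). Over 272 named values, 2316 of 2651 results in other settings kept their direction and side of the threshold, 319 fell short and 16 came past it. Leaving out single libraries gave 1618, 476 and 2 of 2102, with 6 reversed. Called genes among those named passed in each such fit in 41 of 50, 8 of 27, 27 of 46, 25 of 40, 25 of 49, 11 of 32 and 8 of 16 cases for the first 7 comparisons. The list tests past the threshold fell from 56 to 9 of 240 with an estimated correlation. The same-sign share in PBS fish was 97.2% at a mean of at least 10 CPM.

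The replicate number as a block gave 187 (untreated gate), 198 (control gate), 105 (interaction), 22 and 5 (PBS against control) genes, and a same-sign share of 100%. The labels do not say that the number is the fish, so the main fits did not take the numbers as pairs. As deviations from the group means, same-numbered libraries of the gates correlated at 0.00297 to 0.0389, none over 0.1. Yet 24 of 28 libraries correlated best with their own number (8 by chance), which speaks for pairs. The matches are not independent, since each pair was read from both gates and the deviations of the 2 control fish mirror each other. Setting 24 against 8 thus overstates the support. The main fits ignore any pairing, and their counts were 321 (untreated gate), 108 (control gate) and 34 (interaction). The smallest library (2.24 M counts) had 10861 genes with a count, against 9526 to 11149 in untreated ccl34b.1- libraries of 14.2 to 24.0 M, so fewer counts did not go with fewer genes detected there, and what depth limits for low genes was not tested further.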

Other observations

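The ribosomal protein genes and the shared genes named in this part were chosen only after values were seen, while the tests of the 4-month gate genes were set before their results were seen. Ribosomal protein genes were mostly lower in ccl34b.1+ than in ccl34b.1- cells of untreated fish: 79 of 86 had a negative log2 fold change and 7 were past the threshold, all lower. After E. coli 81 of 88 were negative in the gate comparison with 3 past the threshold, all lower, against 62 of 88 in control fish, each short of the threshold, and 59 of 88 in PBS fish, with 1 past it. In ccl34b.1- cells 5 of 88 were negative after E. coli against PBS, and edgeR called none. The median log2 gate differences were -0.86 in untreated, -0.22 in control, -0.14 in PBS and -1.28 in E. coli fish, and the medians of E. coli against PBS were 1.21 in ccl34b.1- and 0.21 in ccl34b.1+ cells (34 of 88 negative). With DESeq2 size factors they were -0.93, -0.40, -0.30, -1.19, 1.00 and 0.22. They took 3.28% and 5.90% of counts in ccl34b.1+ and ccl34b.1- libraries of untreated fish and 1.68% and 3.96% after E. coli. The 3.96% was raised by E. coli ccl34b.1- library 2, at 6.36% against 2.52% and 2.99% in libraries 1 and 3. Libraries 1 and 3 still lay above the PBS ccl34b.1- libraries (0.92% to 2.25%) and the E. coli ccl34b.1+ libraries (1.60% to 1.78%).

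After E. coli 13 genes rose in both gates. Besides NCF1, cxcl8a and mxf these were GPR84, a receptor for medium-chain fatty acids, LACC1, an enzyme of macrophage metabolism, DRAM1, a lysosomal gene of autophagy, FGL2, ATP6V0C ENSDARG00000057853, fth1a, HK2, cxcl11.7, lygl1 and 1 gene with no name. Many of these calls rest on single libraries. In ccl34b.1- cells the adjusted p rose to 0.213 for cxcl8a without E. coli library 1, to 0.151 for mxf without PBS library 1, to 0.101 for LACC1 without PBS library 3, to 0.219 for fth1a without E. coli library 2, to 0.107 for NCF1 without E. coli library 3 and to 0.101 for ATP6V0C ENSDARG00000057853 without PBS library 1. In ccl34b.1+ cells it rose to 0.147 for HK2 without E. coli library 2 and to 0.373 for cxcl11.7 without E. coli library 1. Those that fell in both were tnfsf12, ARPC1B, LCP1, TIMP4 ENSDARG00000100795 and ENSDARG00000080337. Of 87 genes called higher in ccl34b.1+ cells 82.8% had the same sign in ccl34b.1- cells, and of 101 called lower 76.2%. Across all 12421 genes, which are not independent replicates, the log2 fold changes of the 2 gates correlated with r = 0.156.

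A hypothesis was that E. coli moves ccl34b.1+ cells away from the pattern that sets them apart in untreated fish. Genes higher in ccl34b.1+ cells of untreated fish fell as a set after E. coli (camera with an estimated correlation, p = 0.000234, adjusted p = 0.000936 over the 4 tests). Of 173 measured, 140 had a negative value and 25 were called lower, with 1.41 by chance and 0 called higher. The experiments share no library, so the set was chosen on other fish. Genes lower in ccl34b.1+ cells of untreated fish did not rise as a set (camera with an estimated correlation, adjusted p = 0.949): of 138 measured 5 were called higher, with 0.967 by chance, and 7 lower, with 1.12 by chance. These chance values use the share called over all genes, with no match for expression level. The 2 sets were chosen on their level in ccl34b.1+ against ccl34b.1- cells, so part of their contrast may follow expression level, which was not tested. The data may thus be read as a partial loss of the ccl34b.1+ pattern, while a gain of the ccl34b.1- one was not detected for the set as a whole, and a change in which cells fill the gate stays open.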
